A study of Mus musculus with 8 samples.

How the data were processed

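The deposited count file holds integer read counts per gene (unit: count) for 8 libraries, per the file headers, and no normalized values. The authors' deposited tables for males and for females hold, per the file headers, a log2 fold change with its standard error (unit: log2), a test statistic (unit: score), a p-value and an adjusted p-value (unit: p-value). Only genes past 5% are in those tables, so they were not used to count genes that did not change.

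Per the labels' protocols, C-LTMRs were sorted by flow cytometry for GFP from dorsal root ganglia of adult mice, and RNA was extracted with a kit for small samples. Full-length cDNA was made from polyadenylated RNA with SMART-Seq v4 and 13 cycles of PCR. Sequencing libraries were then made with Nextera XT and 12 further cycles, per the labels' protocols. No molecular identifiers were used, so counts include copies made by PCR, and a gene with few starting molecules can appear at a high level in 1 replicate and be absent from the other. Genes with 0 counts in 1 replicate and at least 20 in the other made up 4.7% of male WT genes, 5.66% of male KO, 6.33% of female WT and 6.11% of female KO genes. Replicates of a group differed far more than counting alone would give, with a chi-square per degree of freedom of 105, 287, 136 and 187 in those groups.

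Per the file header, reads were counted with featureCounts 1.6.1 over exons of Ensembl GRCm38 release 97, unstranded, with reads overlapping several genes counted in each. The submitters' processing notes give Subread 1.6.4, bcl2fastq 2.17.1.14 and DESeq2 1.14.1. The names of the aligned files speak of uniquely aligned reads, which lowers the counts of genes with near-identical copies such as the haemoglobin chains. The aligner is not given in the sources used here. Unstranded counting puts reads of antisense pairs such as Xist and Tsix in both genes where exons overlap. Mitochondrially encoded genes had 0 counts in all 8 libraries, so nothing can be said of mitochondrial transcripts or of the share of damaged cells they often track.

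Of the 55573 genes counted, 55394 were found by identifier in the reference annotation for mouse GRCm38, and 99.6% of those had identical coordinates. The remaining 179 kept their identifiers, and 8 of these were tested. Genes were kept by the filterByExpr rule of edgeR, leaving 22013. Library sizes were scaled with TMM factors, which lay between 0.9793 and 1.022. CPM values use the scaled library sizes, and log2 CPM values use a prior count of 2. The 10 most abundant genes took between 4.5% and 5.47% of the counts per library.

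Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust estimation. A fit of 4 groups over all 8 libraries served the comparisons of KO with WT in each sex, the difference between the sexes in that effect, and males against females in each genotype. It left 4 residual degrees of freedom, and all tests were two-sided. KO against WT across both sexes used an additive model of sex and genotype. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes of a comparison. Where a count is said to be adjusted over a list alone, the same edgeR p values were adjusted over the members of that list. Libraries of a group are stated by the submitters to be biological replicates, and p-values rest on that.

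Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, over 26 lists with tested members in 3 comparisons, and adjusted over the 78 tests. Camera asks whether a list ranks above or below other genes, and the preset correlation assumes that members vary nearly independently. Members of a list of cell markers rise and fall together with the share of that cell type, so each call is also given with an estimated correlation. That setting also tests on the 4 residual degrees of freedom of the fit, where the preset one uses the number of genes. A call lost with it can therefore reflect few libraries as well as correlated members. The 27 lists were C-LTMR, peptidergic, nonpeptidergic and myelinated afferent markers, glial, immune, vascular and red blood cell markers, immediate early, heat shock and nerve injury genes, sodium, potassium, calcium and sensing channels, inhibitory receptors, transmitter receptor subunits, vesicle release, cholesterol, interferon and steroid genes, Y-linked and X-linked genes, mitochondrially encoded, oxidative phosphorylation and ribosomal protein genes, and genes within 5 Mb of Bhlha9. Scores of a list are means of log2 CPM over its tested members, centred over the 8 libraries.

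The groups, the comparisons, the lists, the tests, the thresholds, most alternatives and the rule for naming genes were chosen before the data were examined. By that rule Bhlha9, Xist and the Y-linked genes were named in every library. Named next were the largest changes among genes that passed with a mean of at least 5 CPM and no overlap of libraries, up to 4 members per list with the smallest p, and the 5 largest rises and falls of the authors' deposited tables. Th, Calca, Tsix, Kcnq3 and Grm7 with the sexes combined, and the nerve injury genes of the closing section, were named after their values were seen, as were the second sex's values of genes named for the other. The values of 1 list member that the rule would name are not reported here. The list of C-LTMR markers contains Bhlha9 itself, so it is given with and without it.

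The whole procedure was tested on simulated data built on the means and spread of the 8 libraries. For KO against WT in males, 0 of 50 genes changed 2-fold were recovered, 23 of 50 changed 4-fold, 29 of 50 changed 8-fold and 32 of 50 changed 16-fold, with 2 false genes among 86 called. With the sexes combined, 8, 30, 38 and 41 of 50 were recovered, with 5 false genes among 122. For the difference between the sexes, 0, 9, 18 and 27 of 50 were recovered, with 3 false genes among 57. Camera called 100 of 100 shifted lists of 15 genes and 3 of 100 unshifted lists. The simulated genes varied independently, so the camera result does not cover lists whose members vary together. In the real libraries a Y-linked gene differing more than 16-fold between the sexes did not pass, so the recovered shares may be too high.

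Alternatives to each choice were other normalizations, no filter and a stricter filter, DESeq2 1.42.0, a fit without robust estimation, a term for replicate number, each library left out in turn, and only the 4 libraries of a comparison. For lists they were an estimated correlation, the rotation test fry, a term for replicate number and each library left out. Added after results were seen were filters at levels between these, DESeq2 on 4 libraries with and without a prior on fold changes, refits of the authors' tables with all 8 libraries or without each library, and the C-LTMR list without Bhlha9. The model behind the authors' deposited tables is not stated, and the prior was inferred because it returned their fold changes to within 2e-04. Normalization by TMM assumes that most genes do not change, so a shift of all transcripts in the same direction could not be seen. Depth ranged from 50919885 counts in female_KO1 to 71956309 in female_KO2, and replicates still differed beyond counting error by the chi-square values given here. Correlations of log2 CPM between libraries had a median of 0.89 within groups (4 pairs) and 0.894 between groups (24 pairs).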

Results

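C low-threshold mechanoreceptors (C-LTMRs) are unmyelinated sensory neurons of the dorsal root ganglia (DRG) that respond to light touch and carry a tyrosine hydroxylase (Th) and Fam19a4 signature. Gene expression was measured by RNA sequencing in C-LTMRs sorted by their GFP from adult mice. The animals were wild type (WT) or lacked Bhlha9 (KO), a gene for a basic helix-loop-helix transcription factor. Males and females were profiled separately, in a study whose title concerns choice of temperature, pain after formalin and differences between the sexes. Each combination of sex and genotype had 2 libraries, stated by the submitters to be biological replicates, so n = 2 per group and the 8 libraries made up 4 groups. Libraries are named here by sex, genotype and replicate number. The counts assigned to genes were 62633518 and 63055815 in the male WT libraries and 56500253 and 65816312 in the male KO libraries. The female WT libraries held 57882914 and 62892996 counts and the female KO libraries 50919885 and 71956309. Between 22088 genes (female_WT1) and 25131 genes (male_WT2) were detected per library. At these depths 3 counts corresponded to between 0.0417 CPM (counts scaled to library size) in female_KO2 and 0.0589 CPM in female_KO1. Values in CPM are group means with the SD of 2 libraries, and log2 fold changes carry the standard error (SE) of the edgeR fit. The SD and SE reflect the spread between libraries. Floors of 3 counts cover counting error only, and the reads came from amplified cDNA without molecular identifiers.

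Bhlha9 (ENSMUSG00000044243) lies on chromosome 11 from 76672470 to 76673676 on the plus strand of GRCm38. It is a gene of 1 exon of 1207 bp, whose 693 bp of coding sequence run from 76672549 to 76673241, with untranslated stretches of 79 and 435 bp on either side. The transcript stood at 151 and 161 CPM in the male WT libraries and at 140 and 127 CPM in the female WT libraries. In the KO libraries it stood at 0.156 and 0.277 CPM in males and at 0.47 and 0.253 CPM in females. Those levels rested on 9, 18, 24 and 18 counts, against 9550, 10252, 7930 and 8040 counts in the WT libraries, so some reads over the exon remained in every KO library. The genotype stated for all 8 libraries was thus visible in their own reads.

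Bhlha9 fell 721-fold in males (0.217 ± 0.0859 against 156 ± 6.87 CPM, log2 fold change -9.47, SE 0.43, edgeR adjusted p = 0.00344). In females it fell 370-fold (0.361 ± 0.153 against 134 ± 8.89 CPM, log2 fold change -8.56, SE 0.41, edgeR adjusted p = 0.00499). With the sexes combined the log2 fold change was -8.99 (SE 0.34, edgeR adjusted p = 0.000211). The loss was not shown to differ between the sexes (difference -0.91, SE 0.49, edgeR adjusted p = 0.998). The 178 tested genes starting within 5 Mb of Bhlha9 included no gene that passed in either sex. As a list, these neighbours gave adjusted p = 0.45 in males and 0.97 in females. The difference between the sexes for this list gave 0.821.

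The sex stated for each library was also visible in its reads. Xist, the noncoding RNA that coats the inactive X chromosome, stood at 56.6, 67.8, 142 and 20.7 CPM in the female libraries from female_WT1 to female_KO2. In the male libraries it was at most 0.204 CPM. Ddx3y, a Y-linked RNA helicase, stood at 24.6, 19.1, 25.7 and 16.4 CPM in males and at most 0.0587 CPM in females. Eif2s3y, a Y-linked translation factor, stood between 14.9 and 20.3 CPM in males and at most 0.0392 CPM in females. Kdm5d and Uty, Y-linked histone demethylases, had 0 counts in all 4 female libraries. In males Kdm5d ranged from 2.13 to 6.29 CPM and Uty from 0.412 to 7.42 CPM. Counting took no account of strand, so reads of Xist and of its antisense partner Tsix could not be told apart.

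**Figure D1:**
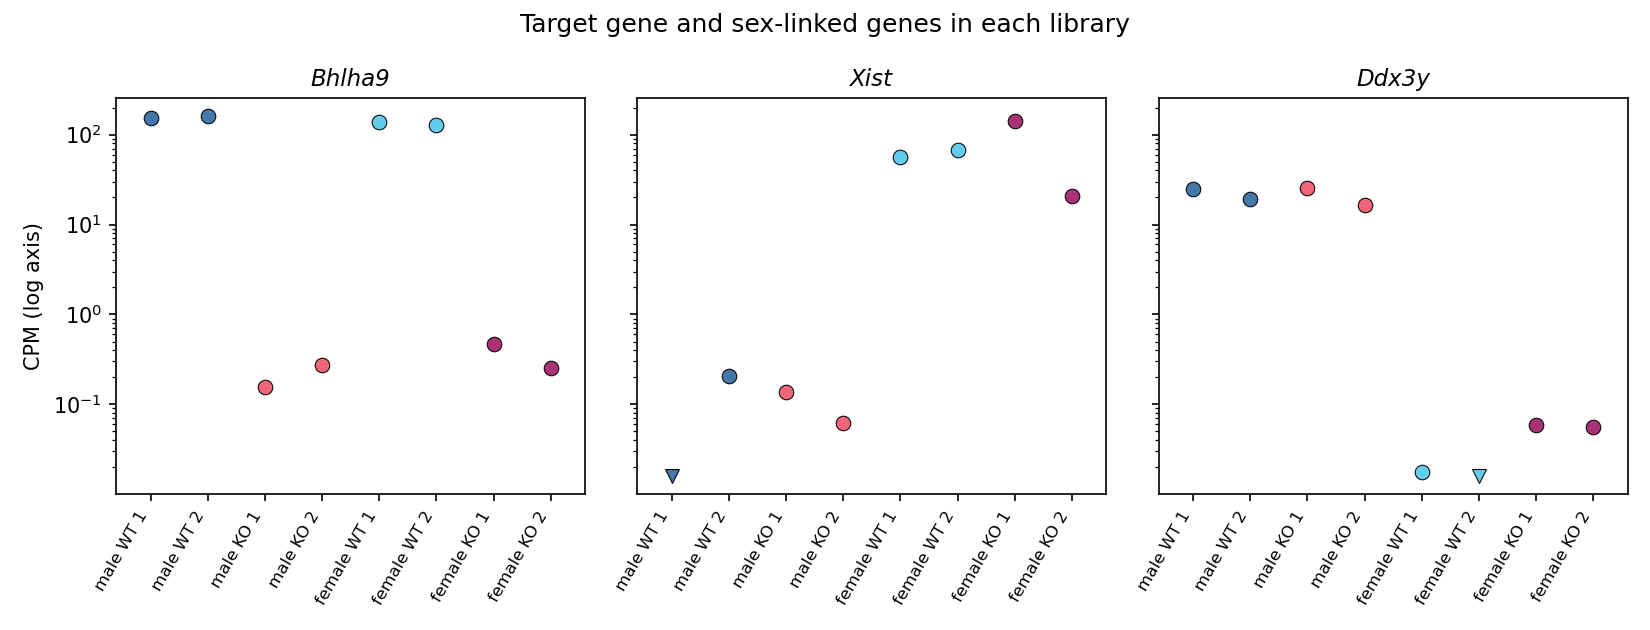
Bhlha9, Xist and Ddx3y in each of the 8 libraries, in CPM on a log axis, with triangles marking libraries with 0 counts drawn at the level of 1 count. Bhlha9 stood at 127 CPM or more in every WT library and at 0.47 CPM or less in every KO library.

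In the male KO libraries, camera at the preset correlation placed C-LTMR markers below other genes, and peptidergic and myelinated afferent markers above them. All 14 tested C-LTMR markers had negative fold changes, with a median of -0.36, and 9 of them had both KO libraries below both WT libraries (16.7% by chance). Both counts include Bhlha9, the deleted gene, and the members were not independent (estimated correlation 0.36). Cacna1h, the T-type calcium channel Cav3.2, went from 123 ± 1.53 to 74.6 ± 2.83 CPM (log2 fold change -0.72, SE 0.17). Runx1, a transcription factor needed for this lineage, went from 231 ± 9.33 to 178 ± 23.4 CPM (-0.38, SE 0.18). Fam19a4 went from 384 ± 59.4 to 279 ± 80.4 CPM (-0.46, SE 0.23). Camera placed the list below other genes at adjusted p = 4.56e-05, or adjusted p = 0.686 with an estimated correlation. Bhlha9 is itself a member, and without it the median of the remaining 13 genes was -0.36 and the adjusted p 0.00286, or adjusted p = 0.686 with an estimated correlation. Those 13 scored -0.5 in male_KO1 and -0.06 in male_KO2, against 0.04 and 0.15 in male WT and -0.09 in female_WT2. The fall was thus mostly that of male_KO1. Bhlha9 was the only member to pass over all genes, and 2 members passed when adjusted over the list alone.

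Peptidergic nociceptor markers rose in males, with 11 of 12 tested members higher in KO and a median log2 fold change of 2.33 (adjusted p = 0.000163, or adjusted p = 0.602 with an estimated correlation). Tac1, the precursor of substance P, went from 151 ± 28.7 to 310 ± 34.1 CPM (1.04, SE 0.29). Calca, the precursor of CGRP and added after its values were seen, was 59.4 and 88.4 CPM in the WT and 579 and 910 CPM in the KO libraries. Myelinated afferent markers rose as well, with 12 of 13 members higher and a median of 2.71 (adjusted p = 0.000338, or adjusted p = 0.686 with an estimated correlation). Nefh, the heavy neurofilament chain, stood at 88.5 ± 22.7 CPM in WT and at 923 ± 888 CPM in KO (3.38, SE 0.78). Pvalb, the parvalbumin of proprioceptors, stood at 1.87 ± 1.18 and 44.7 ± 54.3 CPM (4.57, SE 1.84). The myelinated list lost its call without male_WT2 (adjusted p = 0.137) and without male_KO1 (0.111). Nonpeptidergic and pruriceptor markers were not called (median 1, adjusted p = 0.0571), although Mrgprd stood at 2.32 ± 1.43 and 79.2 ± 58.7 CPM (5.09, SE 2.38). No member of these 3 lists passed over all genes, and Nefh alone passed when adjusted over its list.

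Immediate early genes, which switch on within minutes of stimulation, rose in males, with 16 of 20 higher and a median of 0.83 (adjusted p = 2.53e-05, or adjusted p = 0.686 with an estimated correlation). Ier2 went from 15.4 ± 5.72 to 67.6 ± 10.2 CPM (2.14, SE 0.33). Jun went from 89.8 ± 26.8 to 237 ± 12.6 CPM (1.4, SE 0.38) and Egr1 from 125 ± 18.9 to 224 ± 12.4 CPM (0.84, SE 0.23). Both KO libraries lay above both WT libraries for 12 of the 20 genes, and 5 genes passed when adjusted over the list alone. Without male_WT2 the list gave adjusted p = 0.114. Glia and Schwann cell markers rose, with 13 of 17 higher and a median of 1.42 (adjusted p = 0.000216, or adjusted p = 0.686 with an estimated correlation). S100b, a calcium-binding protein of glia, stood at 14.8 and 4.95 CPM in WT and at 321 and 61.1 CPM in KO. Sox10, a transcription factor of glia, went from 3.69 ± 2.99 to 11.3 ± 0.986 CPM (1.62, SE 0.67). Without male_WT2 the glial list gave adjusted p = 0.287. Vascular and fibroblast markers (adjusted p = 0.0527) and immune cell markers (0.127) were not called.

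In males 2 of the lists of channels and receptors were called. Potassium and HCN channels had 32 of 53 members higher with a median of 0.34 (adjusted p = 0.00467, or adjusted p = 0.49 with an estimated correlation), and without male_KO2 the adjusted p was 0.114. Kcnc4, the potassium channel Kv3.4, went from 5.03 ± 1.3 to 21 ± 6.77 CPM (2.06, SE 0.39), and Kcnq3, an M-current subunit, stood at 0.467 ± 0.304 and 14.7 ± 14.6 CPM (4.97, SE 1.06). Inhibitory G protein coupled receptors had 14 of 20 members higher with a median of 0.74 (adjusted p = 0.0155, or adjusted p = 0.49 with an estimated correlation). Grm4, a metabotropic glutamate receptor, stood at 0.00786 ± 0.0111 and 8.44 ± 1.28 CPM, and the cannabinoid receptor Cnr1 at 0.0551 ± 0.0555 and 5.06 ± 0.262 CPM. The receptor list gave 0.0959 without male_WT2 and 0.128 without male_KO2. Steroid and sex hormone signalling genes had 12 of 14 higher with a median of 0.76 (adjusted p = 0.0155, or adjusted p = 0.49 with an estimated correlation). Hsd17b7, an enzyme of steroid and sterol metabolism, stood at 33.5 ± 3.02 and 55.6 ± 7.96 CPM (0.73, SE 0.27). The steroid list gave 0.0788 without male_WT1, 0.0519 without male_WT2 and 0.171 without male_KO2.

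Nuclear genes of oxidative phosphorylation had 76 of 89 members higher in male KO with a median of 0.22 (adjusted p = 0.00991, or adjusted p = 0.899 with an estimated correlation). Ndufa10, a subunit of respiratory complex I, stood at 259 ± 35.7 and 321 ± 5.99 CPM (0.31, SE 0.16). The call was lost without male_WT2 (adjusted p = 0.775), and without male_KO1 the list turned to the lower side (0.00544). Red blood cell markers were lower, with all 4 members down and a median of -1.65 (adjusted p = 0.0403, or adjusted p = 0.686 with an estimated correlation). Hbb-bs, a chain of adult haemoglobin, was 3.22 ± 3.47 CPM in WT with 0 counts in both KO libraries. The red blood cell list gave 0.775 without male_WT2, 0.404 without male_KO2, 0.0601 without female_WT1 and 0.0731 without female_WT2. The thermal, mechanical and acid sensing channels were not called (adjusted p = 0.0562). Among them Asic3, an acid-gated channel, stood at 0.238 ± 0.336 and 48.8 ± 27.7 CPM (7.67, SE 2.39) and Kcnk4, the mechanically gated channel TRAAK, at 0.792 ± 0.943 and 17.1 ± 1.11 CPM (4.43, SE 1.29).

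Gene by gene, 1 of the 22013 tested genes passed in males, and it was Bhlha9. At an unadjusted p below 0.05, edgeR gave 770 genes against 1101 expected by chance. DESeq2 on all 8 libraries gave 203 genes, 147 higher and 56 lower. Every other gene named here for males had an edgeR adjusted p of 1. The biological coefficient of variation was 76.6%, and in the self-test edgeR recovered 0 of 50 simulated changes of 2-fold and 29 of 50 of 8-fold. Those shares may be too high for the real libraries. Between WT males and females, the Y-linked Ddx3y differed by 11.03 in log2 and did not pass (edgeR adjusted p = 0.0833).

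In the female KO libraries, peptidergic nociceptor markers were lower than in WT, the opposite direction to males. Of the 12 tested members 10 were lower, with a median of -2.8, and 9 had both KO libraries below both WT libraries (16.7% by chance). The members were not independent (estimated correlation 0.22). Gal, the neuropeptide galanin, stood at 44.4 ± 34.3 CPM in WT and 1.01 ± 0.459 CPM in KO (-5.44, SE 1.46). Gpx3, a secreted glutathione peroxidase, stood at 39.4 ± 33.5 and 0.291 ± 0.392 CPM (-7.14, SE 1.5). Kit, the receptor of stem cell factor, stood at 10.3 ± 3.5 and 0.638 ± 0.426 CPM (-4.02, SE 1.17), and the neuropeptide gene Adcyap1 at 19.3 ± 4.91 and 3.74 ± 1.19 CPM (-2.37, SE 0.88). Camera gave adjusted p = 2.53e-05, or adjusted p = 0.508 with an estimated correlation, and 3 members passed when adjusted over the list alone. Without female_KO2 the list gave adjusted p = 0.0852. In that library Calca, named after its values were seen, stood at 5.94 CPM, against 713 CPM in female_KO1 and 351 and 852 CPM in the female WT libraries.

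C-LTMR markers showed no such shift in females. Of the 14 members 11 were higher in KO with a median of 0.13, while the mean was -0.49 because of Bhlha9, and the test lay on the lower side (adjusted p = 0.97). Without Bhlha9 it lay on the higher side (adjusted p = 0.387). Cacna1h went from 128 ± 9.32 to 155 ± 23.4 CPM (0.27, SE 0.17) and Fam19a4 from 288 ± 15 to 360 ± 24.7 CPM (0.32, SE 0.23). Th, the defining enzyme of the class and named after its values were seen, stood between 2980 and 5360 CPM across all 8 libraries.

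**Figure D2:**
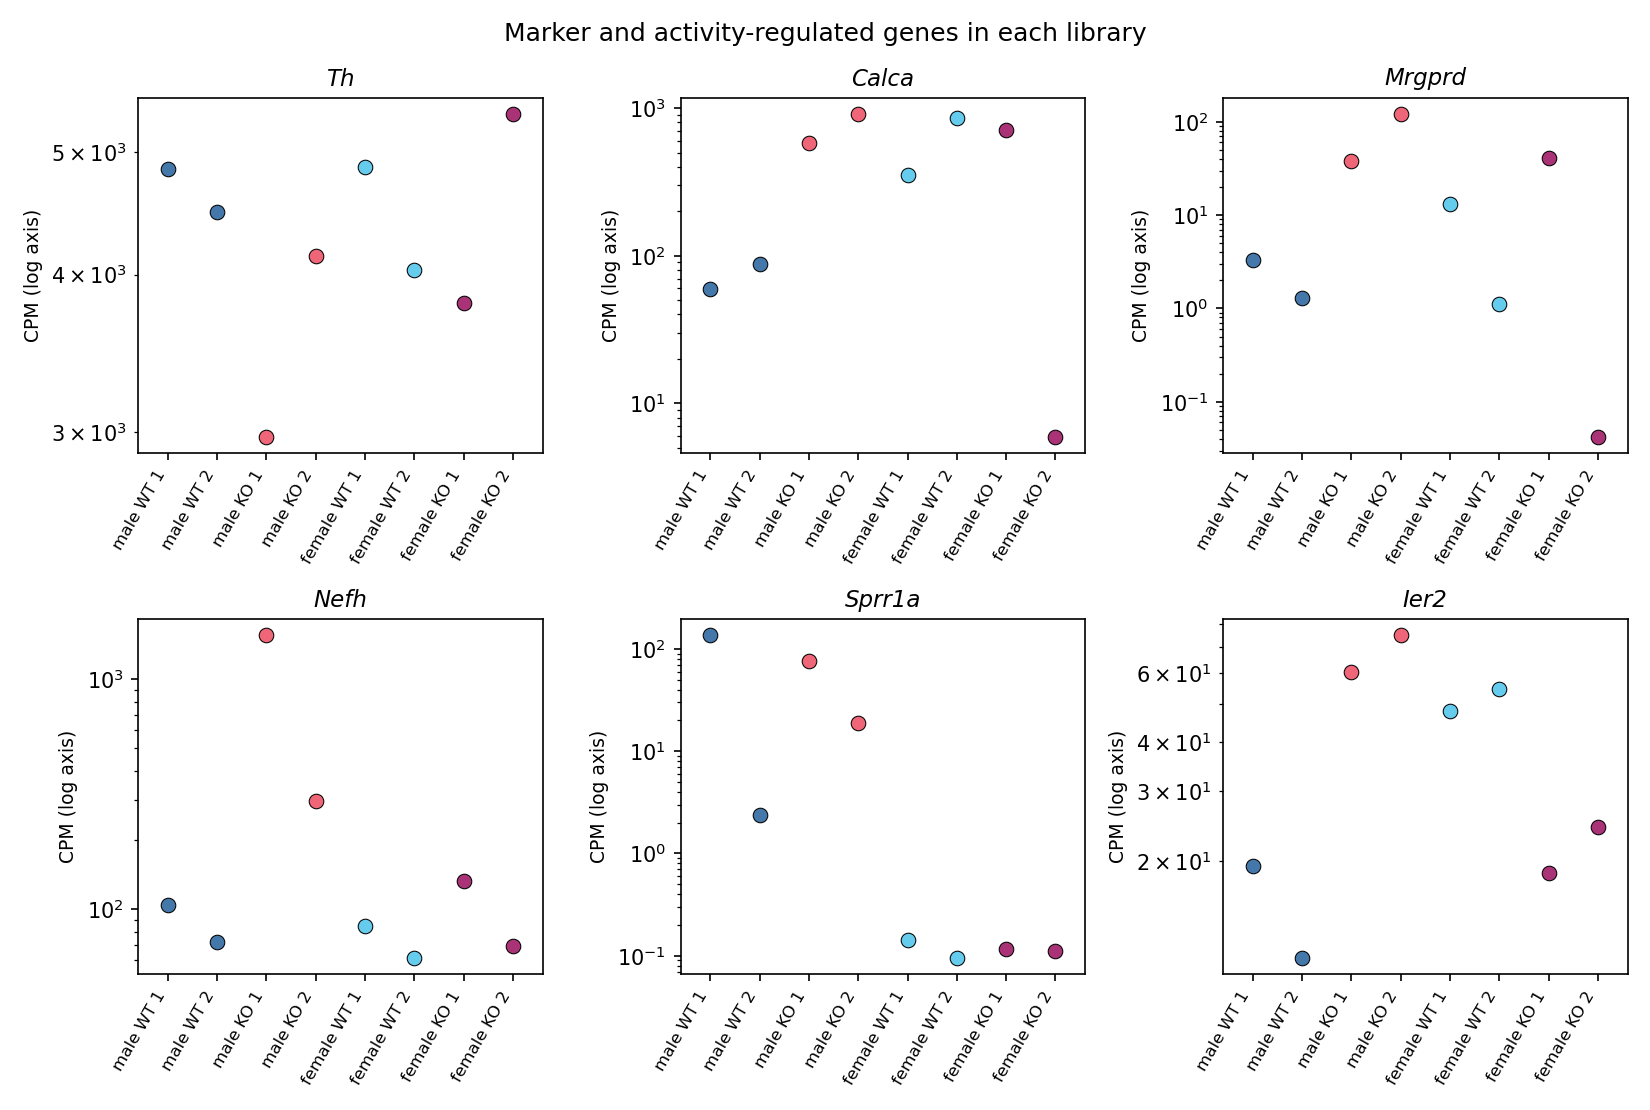
Th, Calca, Mrgprd, Nefh, Sprr1a and Ier2 in each library, in CPM on a log axis, by sex and genotype. Calca reached 579 and 910 CPM in the male KO libraries and 5.94 CPM in female_KO2.

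Glia and Schwann cell markers were lower in female KO, with 15 of 17 members down and a median of -0.63 (adjusted p = 0.0238, or adjusted p = 0.844 with an estimated correlation). Sox10 went from 6.05 ± 0.13 to 1.62 ± 0.596 CPM (-1.9, SE 0.68) and Kcnj10, a potassium channel of satellite glia, from 10 ± 1.32 to 5.01 ± 1.27 CPM (-1, SE 0.59). The call was lost without male_KO2 (adjusted p = 0.0555), without female_WT2 (0.251) and without female_KO1 (0.819). Immediate early genes were lower, with 17 of 20 down and a median of -0.29 (adjusted p = 0.0403, or adjusted p = 0.899 with an estimated correlation). Ier2 went from 51.3 ± 4.65 to 21.5 ± 4.05 CPM (-1.26, SE 0.32) and Zfp36, which speeds decay of inflammatory mRNAs, from 99.3 ± 30.1 to 57.7 ± 18.1 CPM (-0.78, SE 0.35). This call was lost without male_KO2 (0.0589) and without female_KO1 (0.786), and without female_WT2 the list turned to the higher side (0.985).

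Myelinated afferent markers (adjusted p = 0.18, median -0.8) and nonpeptidergic markers (0.97) were not called in females, and Etv1 alone of the former passed when adjusted over its list.

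Single genes in females are given here, from lists that were not called. The thermal, mechanical and acid sensing channels and the X-linked genes each gave camera adjusted p = 0.97. Potassium and HCN channels gave 0.798 and inhibitory receptors 0.647. Trpm2, a heat-activated channel, went from 1.13 ± 0.00795 to 8.2 ± 3.68 CPM (2.85, SE 0.54) and passed when adjusted over the list of thermal, mechanical and acid sensing channels alone. Kcnk3, the leak channel TASK-1, stood at 21.3 ± 2.85 and 6.81 ± 1.88 CPM (-1.64, SE 0.37). Grm7, a metabotropic glutamate receptor, stood at 6.14 ± 1.11 and 17.3 ± 4.29 CPM (1.5, SE 0.33). Kdm6a, a histone demethylase that escapes X inactivation, went from 3.6 ± 0.345 to 16.1 ± 0.572 CPM (2.16, SE 0.48) and passed when adjusted over the list of such X-linked genes alone. Over all genes 1 gene passed in females, Bhlha9. edgeR gave 838 genes at an unadjusted p below 0.05 and DESeq2 on all 8 libraries gave 236, 112 higher and 124 lower. The other genes named here for females had an edgeR adjusted p of 1.

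The effect of losing Bhlha9 was then compared between males and females, with positive values standing for a higher KO to WT ratio in males. Peptidergic markers differed most, with 11 of 12 members positive and a median difference of 5.14 (adjusted p = 2.15e-07, or adjusted p = 0.49 with an estimated correlation), and 6 members passed when adjusted over the list alone. The difference was 10.39 (SE 1.93) for Gpx3, 6.59 (SE 1.86) for Gal and 1.74 (SE 0.41) for Tac1. By camera p, though not by median, immediate early genes followed, with 18 of 20 positive and a median of 1.02 (adjusted p = 2.53e-05, or adjusted p = 0.686 with an estimated correlation). Ier2 differed by 3.39 (SE 0.46). Glial markers had a median difference of 2.1 (adjusted p = 4.87e-05, or adjusted p = 0.686 with an estimated correlation), and Sox10 differed by 3.52 (SE 0.96). These 3 calls held without any single library. C-LTMR markers were negative in all 14 cases with a median of -0.47 (adjusted p = 0.00384, or adjusted p = 0.686 with an estimated correlation), and Cacna1h differed by -0.99 (SE 0.24). That call was lost without male_KO1 (adjusted p = 0.152) and without female_WT2 (0.116), and without Bhlha9 the list gave 0.0073, or adjusted p = 0.686 with an estimated correlation. Myelinated markers had a median of 4.59 (adjusted p = 0.000875, or adjusted p = 0.686 with an estimated correlation) and were lost without male_WT2 (0.0562). Etv1, a transcription factor of proprioceptors, differed by 9.69 (SE 1.53).

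Another 5 lists were called for the difference between the sexes, each on the male side. Oxidative phosphorylation genes had 80 of 89 members positive with a median of 0.36 (adjusted p = 0.00312, or adjusted p = 0.899 with an estimated correlation). They were lost without male_WT2 (0.238) and female_KO2 (0.116), and turned negative without male_KO1 (0.582). Potassium and HCN channels had a median of 0.27 (adjusted p = 0.0324, or adjusted p = 0.49 with an estimated correlation), with Kcnc4 differing by 2.84 (SE 0.54). Without male_KO2 they gave 0.134, without female_WT1 0.153 and without female_KO1 0.0512. Steroid and sex hormone signalling genes had a median of 1.09 (adjusted p = 0.0184, or adjusted p = 0.49 with an estimated correlation). Without male_WT1 they gave 0.0644, without male_KO2 0.129 and without female_KO2 0.0661. Inhibitory receptors had a median of 0.89 (adjusted p = 0.041, or adjusted p = 0.508 with an estimated correlation). Without male_WT2 they gave 0.092, without male_KO2 0.134, without female_WT2 0.39 and without female_KO2 0.105. Vascular and fibroblast markers had a median of 4.08 (adjusted p = 0.034, or adjusted p = 0.686 with an estimated correlation). Without male_WT2 they gave 0.137, without male_KO1 0.277, without female_WT2 0.122, without female_KO1 0.0655 and without female_KO2 0.214.

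No single gene passed for the difference between the sexes. The smallest edgeR adjusted p was 0.98, with 1041 genes at an unadjusted p below 0.05, while DESeq2 gave 284 genes, 210 positive and 74 negative. None of the 23 list calls in these 3 comparisons held with an estimated correlation, where the smallest adjusted p was 0.49. Potassium and HCN channels, inhibitory receptors and steroid genes had estimated correlations of -0.01, 0 and -0.03, not above the preset 0.01. The loss of those calls therefore does not show that their members varied together. The estimated setting also tests on 4 residual degrees of freedom rather than on the number of genes. The rotation test fry, which asks whether genes of a list move on balance one way and does not compare them with other genes, gave smallest adjusted p values of 0.104 in males, 0.484 in females and 0.104 for the difference. Its mixed form, which counts movement in either direction, gave 0.000659 in males and 0.000529 in females, both for the C-LTMR list that contains Bhlha9, and 0.00183 for sensing channels in the difference. Without Bhlha9 the mixed form gave adjusted p = 0.368 in males and 0.885 in females for C-LTMR markers. The smallest values were then 0.0178 in males, for sensing channels and for genes near Bhlha9, 0.00687 in females for inhibitory receptors and 0.00548 for sensing channels in the difference.

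**Figure D3:**
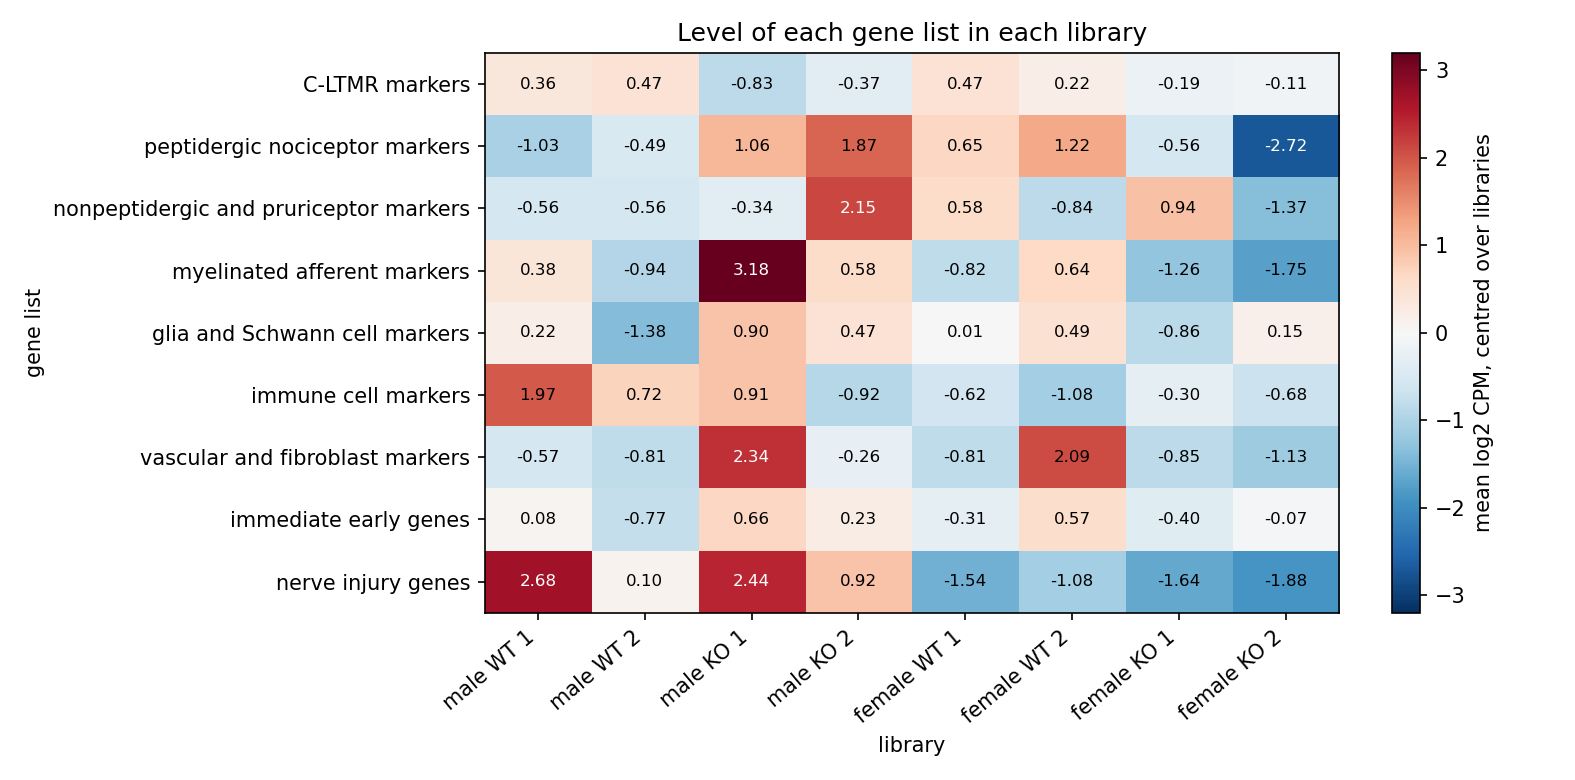
Mean log2 CPM of 9 marker lists in each of the 8 libraries, each list centred on its mean over the libraries, with Bhlha9 counted among the C-LTMR markers. Peptidergic markers stood at 1.06 and 1.87 in the male KO libraries and at -0.56 and -2.72 in the female KO libraries.

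Marker scores varied between libraries of the same group as well as between groups. Myelinated afferent markers scored 3.18 in male_KO1 and 0.58 in male_KO2, while nonpeptidergic markers scored -0.34 and 2.15. Vascular and fibroblast markers scored 2.34 in male_KO1 and 2.09 in female_WT2, and lay between -1.13 and -0.26 in the other 6 libraries. Immune cell markers were highest in male_WT1 (1.97) and red blood cell markers in male_WT2 (3.95). Glial markers were lowest in male_WT2 (-1.38). C-LTMR markers without Bhlha9 were lowest in male_KO1 (-0.5), while male_KO2 (-0.06) lay within the range of the other 6 libraries, from -0.09 to 0.23.

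Of the 27 lists, 16 were called in none of the 3 comparisons, and the mitochondrially encoded genes among them could not be tested because all 37 had 0 counts in every library. In males heat shock genes gave adjusted p = 0.334, nerve injury genes 0.495 and synaptic vesicle release genes 0.495. Glutamate, GABA and glycine receptor subunits gave 0.334. Voltage-gated sodium channels, voltage-gated calcium channels, cholesterol synthesis genes, interferon and antigen presentation genes and cytosolic ribosomal protein genes each gave 0.97. X-linked genes expressed from the inactive X gave 0.97 and Y-linked genes 0.798. The 15 tested lists lay between 0.0671 and 0.97 in females, with interferon genes at the lower end. For the difference between the sexes they lay between 0.158 and 0.97.

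Beyond Bhlha9 no gene passed with the sexes combined. edgeR gave 1 gene there, with 783 at an unadjusted p below 0.05, while DESeq2 gave 161, 73 higher and 88 lower. Among list members, Kcnq3 stood at 0.529 ± 0.243 CPM in WT and 9.81 ± 10.2 CPM in KO (4.01, SE 0.79), and Grm7 at 9.07 ± 3.5 and 20.8 ± 5.12 CPM (1.25, SE 0.23). For both genes all 4 KO libraries lay above all 4 WT libraries, and the edgeR adjusted p was 1.

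Males and females were also compared within each genotype. In WT, Ddx3y stood at 21.9 ± 3.94 CPM in males and 0.00882 ± 0.0125 CPM in females (log2 fold change 11.03, SE 0.81, edgeR adjusted p = 0.0833), the smallest adjusted p of that comparison. Eif2s3y differed by 8.9 (SE 0.9, edgeR adjusted p = 0.34) and Xist by -9.22 (SE 1.46, edgeR adjusted p = 0.903). In KO the smallest adjusted p was 0.156, again for Ddx3y (8.47, SE 0.68). No gene passed in either comparison with edgeR, where 977 genes in WT and 934 in KO had an unadjusted p below 0.05, and DESeq2 gave 187 and 295. Without a filter on low counts, edgeR called 3 genes in each comparison. They were Ddx3y (adjusted p = 0.00515 in WT and 0.0127 in KO), Eif2s3y (0.0275 and 0.0194) and Tsix (0.0334 and 0.0307). Ddx3y, Eif2s3y and Tsix were therefore missed with the default filter and called without it. The stricter filter called the same 3, while Xist, Kdm5d and Uty were called with none of these settings. The fit borrowed less between genes under the default filter, with median prior degrees of freedom of 2.71. They were 5.7 without a filter and 5.52 with the stricter one, which was looked at after the counts were seen.

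The authors' deposited table for males held 150 genes at their threshold of 5%, 140 higher and 10 lower in KO. Its largest rises in the authors' deposited table were Ly86 (log2 fold change 3.54), Lrrn2 (3.12), Tmem233 (2.97), Plekhg1 (2.93) and Htra1 (2.84). The largest falls in the authors' deposited table were Bhlha9 (-7.40), Penk (-3.15), Gpatch3, Hook2 and Scarb1. In the counts, Ly86, a secreted partner of an immune receptor, stood at 2.04 ± 0.00148 CPM in WT and 89.3 ± 58.7 CPM in KO. Lrrn2, a leucine-rich repeat membrane protein, stood at 0.0157 ± 0.0222 and 10.2 ± 1.09 CPM, and Tmem233 at 3.12 ± 1.35 and 58.7 ± 19.6 CPM. Plekhg1 had 0 counts in both WT libraries (3-count floors of 0.0479 and 0.0476 CPM) and 9.12 ± 0.755 CPM in KO. Htra1, a secreted protease, stood at 3.97 ± 0.918 and 54.3 ± 18.4 CPM. Penk, the precursor of enkephalins, stood at 18.5 ± 4.15 and 0.675 ± 0.148 CPM. Hook2 went from 24.7 ± 1.97 to 5.8 ± 1.15 CPM, Gpatch3 from 9.06 ± 2.38 to 1.12 ± 0.357 CPM and Scarb1 from 12.7 ± 4.78 to 2.39 ± 0.171 CPM.

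The authors' deposited table for females held 13 genes, 3 higher and 10 lower. The rises in the authors' deposited table were Wdfy4 (1.46), Kdm6a (1.27) and Zmat1 (1.25). Its largest falls in the authors' deposited table were Bhlha9 (-6.05), Ift122 (-1.85), Gal (-1.81), Etv1 (-1.61) and Adcyap1 (-1.25). In the counts, Wdfy4 stood at 0.307 ± 0.0593 CPM in WT and 8.58 ± 2.06 CPM in KO, and Zmat1 at 2.13 ± 0.0735 and 11.8 ± 0.643 CPM. Ift122, a part of the transport complex of cilia, stood at 25.8 ± 0.54 and 3.19 ± 0.739 CPM. Etv1 stood at 15.2 ± 10.1 and 0.213 ± 0.0033 CPM.

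Both tables were rebuilt exactly from the counts with DESeq2 and a prior on fold changes, 150 of 150 and 13 of 13 genes, using the 4 libraries of each sex. In the edgeR fit every one of these genes had the same sign, and 113 of the 150 and 12 of the 13 had an unadjusted p below 0.05. Bhlha9 alone passed edgeR's adjustment in each. The rebuilt male count was 67 without male_WT2 and 914 without male_KO2, against 135 and 158 without the other libraries. The rebuilt female count was 5 without female_WT2 and 46 without female_WT1, against 21 and 22 without the others. With all 8 libraries in the same model the counts were 93 for males and 49 for females. Parting the 4 libraries of a sex into 2 pairs across genotype gave 54 and 16 genes in males and 77 and 83 genes in females.

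**Figure D4:**
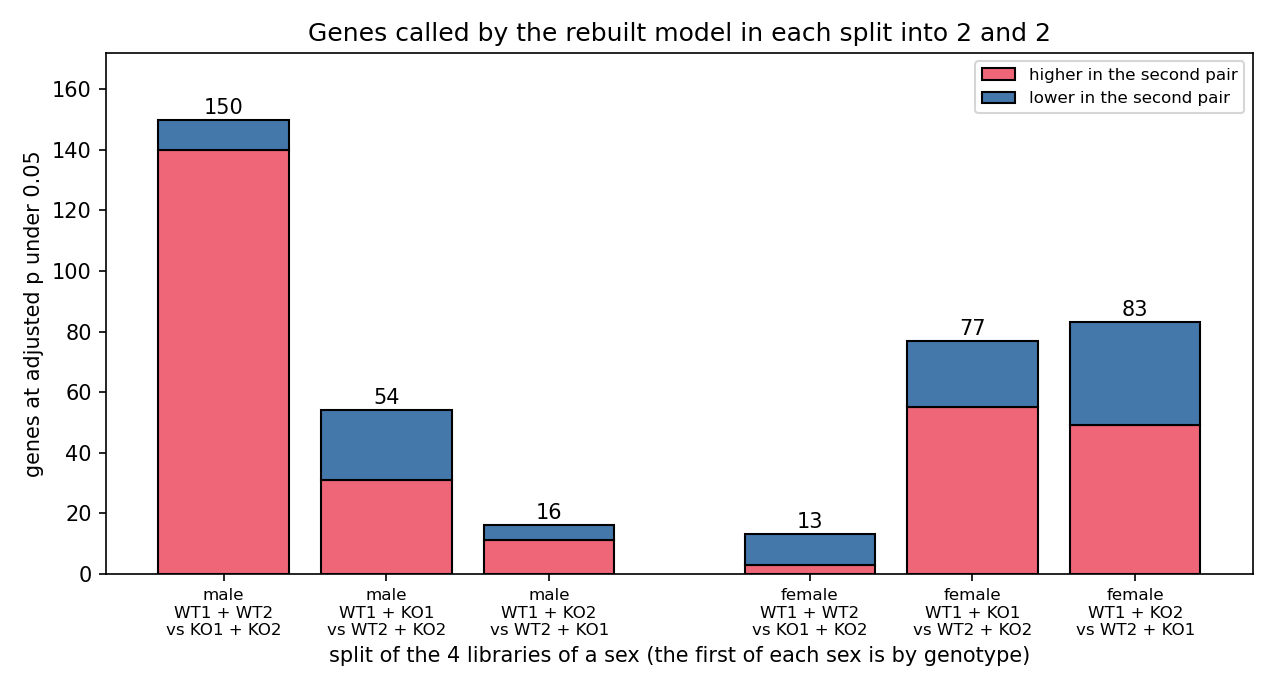
Number of genes past 5% with the authors' model when the 4 libraries of a sex are parted into 2 pairs in each possible way, stacked by direction. The true genotype split gave 150 genes in males and 13 in females, against 83 for female_WT1 and female_KO2 against the other female libraries.

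The sexes shared few of these genes. Bhlha9 and Etv1 were in both tables (0.089 genes expected by chance over the genes tested with edgeR). Bhlha9 was there because it was deleted, and Etv1 was higher in male KO and lower in female KO. Of the 149 genes of the male table other than Bhlha9, 53 had the same sign in females. An unadjusted edgeR p below 0.05 in females, in either direction, was found for 25 of the 149, against 838 of all 22013 tested genes. Of the 12 genes of the female table other than Bhlha9, 3 had the same sign in males. An unadjusted edgeR p below 0.05 in males was found for 3 of the 12. Penk stood at 15.5 and 21.4 CPM in the male WT libraries and 0.78 and 0.57 CPM in the male KO libraries. In females it stood at 0.0353 and 0.253 CPM in WT and at 3.43 and 1.04 CPM in KO. Kdm6a, higher in female KO, stood at 10.7 and 5.71 CPM in male WT and at 9.19 and 17.4 CPM in male KO. Across the 11857 genes other than Bhlha9 with a mean of 5 CPM or more, the male and female fold changes had the same sign for 47.3%.

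**Figure D5:**
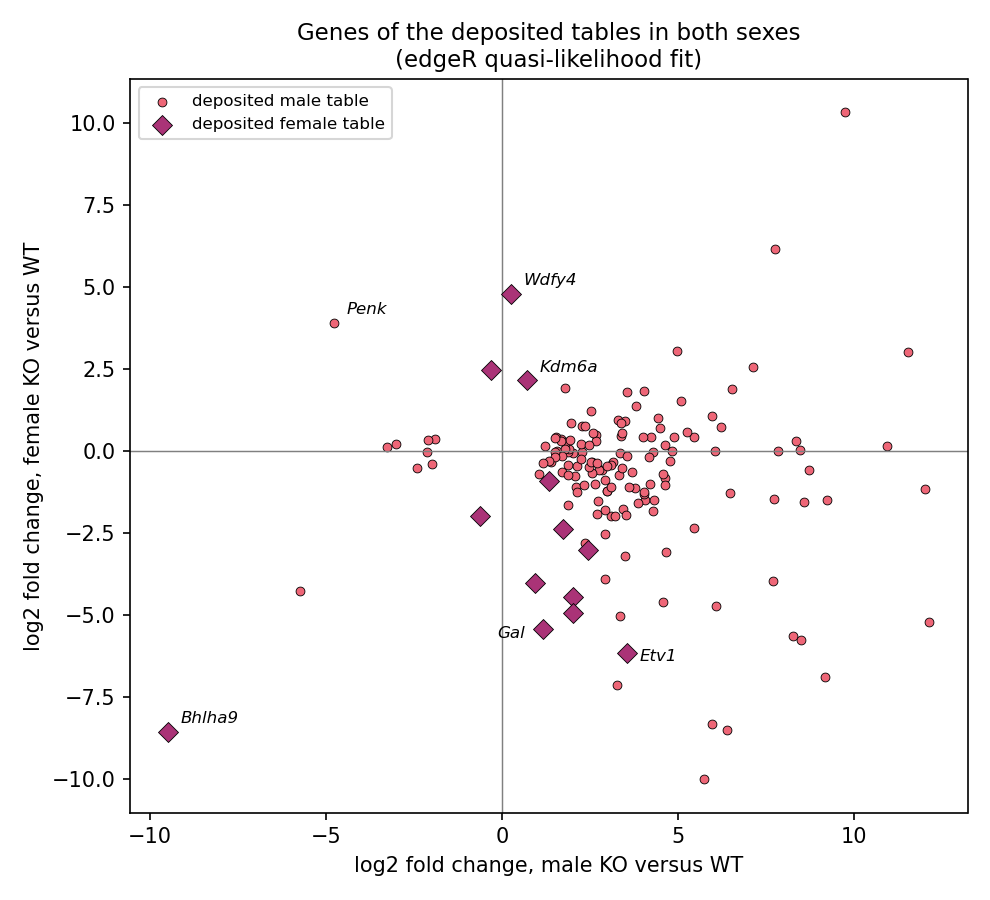
Log2 fold change, KO against WT, in males (horizontal) and females (vertical) for the genes of the authors' deposited tables, with circles for the male table and diamonds for the female table. Genes in both tables, Bhlha9 and Etv1, are drawn as diamonds, and 53 of 149 circles other than Bhlha9 share a sign.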

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

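The count over other splits with the sexes combined, the random lists matched for selection and the gap between the female KO libraries were tests chosen after the result was seen, while the other tests here were written down before their values were seen.

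Peptidergic markers, immediate early genes and glial markers were called in both sexes, in opposite directions, and 7 further lists were called for the difference between the sexes without a call in females. For the difference between the sexes, peptidergic markers gave camera adjusted p = 2.15e-07, immediate early genes 2.53e-05, glial markers 4.87e-05 and myelinated afferent markers 0.000875. Oxidative phosphorylation genes gave 0.00312 and C-LTMR markers 0.00384. Steroid and sex hormone signalling genes gave 0.0184, potassium and HCN channels 0.0324, vascular and fibroblast markers 0.034 and inhibitory receptors 0.041. All 10 were lost with an estimated correlation, where the smallest adjusted p for this comparison was 0.49.

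For the male table, the authors' model was given every way of parting the 4 male libraries into 2 pairs, to see what an arbitrary grouping yields. The real pairs gave 150 genes and the best other pairs 54, so 1 of 3 splits reached the real count, too few splits to tell. RNA from other sensory neurons in the male KO libraries could raise such genes without any change in C-LTMRs. Nefh reached 1551 and 296 CPM there, while Calca, at 579 and 910 CPM, was about as high in female_WT2 (852 CPM) and female_KO1 (713 CPM) and low in male WT (59.4 and 88.4 CPM). That explanation predicts that the 140 higher genes follow markers of other sensory neurons in the 6 libraries that are not male KO. Over the 115 of them outside all lists, r was 0.87 (exact permutation p = 0.00417, adjusted 0.00834) and rho 0.94 (exact permutation p = 0.0167, adjusted 0.0334), in a family of 2 relations, with r = 0.77 without female_KO2 and female_WT2. The 140 genes were partly chosen for being low in the male WT libraries, which are 2 of the 6 libraries and 2 of the 4 behind the r of 0.77, so these p-values are not independent evidence.

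Random lists matched for level alone, with a 95th percentile of 0.73, do not share that selection. Lists matched gene by gene for level, for male WT against female level and for male KO against male WT had a median r of 0.42 and a 95th percentile of 0.6, and the r of 0.87 exceeded 100% of 10000 such lists. Their male KO minus WT difference was 3.09, against 3.59 for the 115 genes, so the match was not full. Markers of other sensory neurons, 38 genes of 3 lists, scored 1.3 and 1.53 in the male KO libraries and -1.95 in female_KO2. Of these markers 10 were in the deposited male table themselves, so their score shares part of the selection and is not independent of that table. The 115 genes scored 2.46 and 2.13 in male KO and -1.82 in female_KO2, a gap of -1.65 to female_KO1 that 0% of the matched lists reached (median -0.12), so within females the relation rests on that library. None of the 38 genes is a C-LTMR marker, and 24 stood above 5 CPM on average in the WT libraries, so their RNA was present without the KO as well. A sort for GFP would remove cells without it, but a change of C-LTMRs toward other sensory fates, or GFP in more cell types, might give the same correlation, and the explanations stay open.

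For the female table, the real pairs gave 13 genes while the other pairs gave 77 and 83, so 3 of 3 splits reached the real count. Parting the libraries across genotype thus gave more genes than genotype did. With 3 splits, noise between libraries and a structure of the samples could not be told apart. RNA from other sensory neurons in the female WT libraries could set apart Gal, Etv1, Adcyap1 and Kit, markers of those neurons among the 10 lower genes, but Gal stood at 0.685 CPM in female_KO1 and 1.33 CPM in female_KO2 although female_KO1 kept Calca at 713 CPM. Over the 5 lower genes outside all lists, r was 0.62 (exact permutation p = 0.186, adjusted 0.186) and rho 0.71 (exact permutation p = 0.136, adjusted 0.136) across the 6 libraries that are not female KO, with 0.98 without male_KO2 and male_KO1. Random lists matched for level alone reached 0.78 at the 95th percentile, so the test could not tell. The 5 genes were partly chosen for being high in the female WT libraries. Those libraries are among the 6 and stay in the r of 0.98, so these values are not independent evidence.

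With the sexes combined, edgeR called 1 gene, Bhlha9. All 34 splits of the 8 libraries into 4 and 4 other than by sex were fitted in the same way to see what an arbitrary grouping yields. The true split was 1 of 34 to reach that count, and the highest count among the others was 0. Only the split by genotype parts the libraries by Bhlha9, so this adds nothing to the levels of that gene in each library.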

How the results depend on the processing

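The filters between the planned levels, DESeq2 on 4 libraries with and without a prior, every refit of the authors' tables and the C-LTMR list without Bhlha9 were tests chosen after results were seen. For KO against WT in males, edgeR called 1 gene, DESeq2 203, and both the replicate block within sex and a fit of only the 4 male libraries 0. DESeq2 on those 4 libraries called 375 genes, and 150 with the prior. In females, edgeR called 1 gene, DESeq2 236, and a block of replicate number, a block within sex and only 4 libraries each gave 0. DESeq2 on the 4 female libraries called 156, and 13 with the prior. Leaving out single libraries kept both counts at 1. Bhlha9 kept its fold change where it lost its call, with adjusted p = 0.126 in males and 0.161 in females under the block within sex. With only 4 libraries it gave 0.0593 and 0.175, and 0.0536 in females with a block of number. DESeq2 raised the counts to 284 for the difference between the sexes and 161 for the sexes combined.

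For males against females, no filter gave 3 genes in WT and 3 in KO, and the stricter filter 3 and 3. A filter of 1 CPM gave 1 gene in WT, one of 2 CPM gave 1 in each, and DESeq2 gave 187 and 295. The authors' male table, rebuilt, ranged from 67 genes (46 of the 150 kept) without male_WT2 to 914 (117 kept) without male_KO2, and held 93 (62 kept) with all 8 libraries. The female table ranged from 5 (2 of the 13 kept) without female_WT2 to 46 (7 kept) without female_WT1, and held 49 (6 kept) with all 8. The 23 list calls became 0 with an estimated correlation and 0 with fry. They ranged from 15 (12 kept) without male_WT2 to 30 (19 kept) without male_KO1, and with the block of replicate number were 22 (21 kept). Oxidative phosphorylation genes in males ranged from adjusted p = 2.78e-12 without male_KO2 to 0.775 without male_WT2 and turned sign without male_KO1 (0.00544). For the difference between the sexes they ranged from 6.33e-12 without male_KO2 to 0.582 without male_KO1, where they turned sign. Immediate early genes in females ranged from 0.000751 without female_WT1 to 0.985 without female_WT2, where they turned sign. Whether replicate numbers pair libraries was checked by correlating deviations from group means, which for equal numbers gave -0.01 between male groups and 0 between female groups, and between -0.1 and 0.11 for groups of different sex, so no pairing by number was seen. The cause of these shifts was not tested. Depth limits detection to 3 counts, at most 0.0589 CPM, and the effect of more replicates was not tested.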

Other observations

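The comparisons by sex of list scores and the counts of fully separated genes over splits were chosen after the result was seen, and so were the genes named in this part.

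Some nerve injury genes were higher in the male than in the female libraries. The 16 tested members were not independent (estimated correlation 0.31). Of them, 5 had all 4 male libraries above all 4 female libraries (1.43% by chance), namely Sprr1a, Ecel1, Anxa1, Flrt3 and Stmn4. The other 11 overlapped, among them Atf3, a transcription factor induced by axon damage, at 207, 74.8, 246 and 121 CPM in males and 68, 126, 82.8 and 162 CPM in females. The list's mean score was 1.53 in males and -1.53 in females, a difference of 3.07, and all 4 male libraries lay above all 4 female libraries. Sprr1a, a protein of regenerating axons, stood at 136, 2.37, 75.3 and 18.8 CPM from male_WT1 to male_KO2 and at no more than 0.141 CPM in any female library. Ecel1, a protease gene induced by axon damage, stood at 34.5, 2.37, 13.5 and 9.87 CPM in males and had 0 counts in 3 female libraries. Nts, which encodes neurotensin, stood at 51.3, 0.0314, 10.7 and 5.83 CPM in males and at most 0.0392 CPM in females. Anxa1, an annexin that restrains inflammation, ranged from 0.339 to 20.5 CPM in males and was at most 0.0392 CPM in females. Npy, neuropeptide Y, was uneven, with 7.64 CPM in male_WT1, 113 CPM in male_KO1 and 0.0634 CPM or less elsewhere. The exact permutation p for the score was 0.0286, the smallest possible with 4 against 4, and 0.248 when adjusted over 26 lists. Y-linked genes (difference 7.48) and X-linked genes (-1.58) were also fully separated and gave the same permutation p. At its smallest possible value, that p does not measure how wide a gap was. Whether the male animals differed in age, housing or handling is not stated, nor whether batches of dissection followed sex. Such differences could not be told apart from sex.

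Genes with all KO libraries on 1 side of all WT libraries were no more frequent than chance. Levels were not centred by sex, so genes moving the same way in both sexes from different levels can be missed. Among 11873 genes with a mean of 5 CPM or more, here taken from log2 values with the prior count and with Bhlha9 included, 226 had all 4 KO libraries on 1 side of all 4 WT libraries, 114 higher and 112 lower, against 339 expected by chance. Of the 35 ways to part 8 libraries into 4 and 4, 27 gave at least as many genes. Grm7 was among the 114, at 11.3 and 12.7 CPM in male WT, 26.7 and 21.8 CPM in male KO, 6.92 and 5.35 CPM in female WT and 20.4 and 14.3 CPM in female KO. Parting by sex gave 389 genes, a count that 8 of the 35 splits reached.

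The largest count, 1677 genes, came from a split of neither sex nor genotype, with male_WT1, male_WT2, male_KO2 and female_KO2 against the other 4 libraries, while the median of the other splits was 284. The 910 genes lower on the first side had a median exon length of 1480 bp, against 3795 bp for the 767 higher genes and 4436 bp for the remaining 10196. Among the lower genes were 55 of 76 oxidative phosphorylation genes and 30 of 62 ribosomal protein genes at this level, and among the higher ones 2 and 0. The median differences were -0.57 and 0.52 in log2. Oxidative phosphorylation genes scored 0.4 in male_KO1 and -0.49 in male_KO2, with -0.18 and -0.38 in the male WT libraries. The positive call for this list in male KO turned negative without male_KO1 (adjusted p = 0.00544), was lost without male_WT2 (0.775) and gave adjusted p = 0.899 with an estimated correlation. Nothing in the labels names what the 4 libraries shared.

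Some transcripts of other sensory neurons differed widely between the 2 female KO libraries, which share a genotype. Peptidergic markers scored -0.56 in female_KO1 and -2.72 in female_KO2, and nonpeptidergic markers 0.94 and -1.37. Myelinated afferent markers were closer, at -1.26 and -1.75, and Etv1 stood at 0.215 and 0.211 CPM. Mrgprd, a receptor of nonpeptidergic nociceptors, stood at 41.2 CPM in female_KO1 and 0.0421 CPM in female_KO2, and Calca at 713 and 5.94 CPM. In the same libraries Th stood at 3800 and 5360 CPM and C-LTMR markers without Bhlha9 scored 0.08 and 0.23. The female WT libraries differed too, with Mrgprd at 13.1 and 1.12 CPM. The male KO libraries were uneven in another way, with Nefh at 1551 and 296 CPM and Mrgprd at 37.7 and 121 CPM. Immediate early genes differed by 0.79 between male KO and WT, and by 0.85 between the 2 male WT libraries alone. In females the genotype difference was -0.36, beside gaps of 0.89 within WT and 0.33 within KO.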
